A study of Homo sapiens with 6 samples.

How the data were processed

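Total RNA from A549 cells was extracted with TRIzol and 1.3 ug per sample went into standard Illumina libraries, per the labels' protocols. The 6 samples fall into 2 groups by the treatment given in the labels, DMSO and BRQ, with 3 samples each. The submitters' processing notes name fastp, HTSeq and the genome build hg38, without versions; the aligner, the gene annotation and the strand setting are not given in the sources used here. The deposited table gives FPKM values for 17335 genes in 6 columns, 1 per sample, with Entrez gene IDs and annotation terms. FPKM, per the name of the deposited table and its values, is the number of fragments scaled to gene length and to a read total per library. No further scaling between libraries was seen. All 6 columns matched a sample and were used.

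The depth was worked out from the values. Within a gene, FPKM values are whole multiples of what 1 read is worth, and a common solution for gene lengths and library totals gave whole reads for all 17335 genes (each value within 0.01 of a whole read) and gene lengths within 0.05 bases of a whole number for 99.8% of genes. The library totals came to 27789225, 29644462 and 28527046 reads in DMSO and 32910420, 32195353 and 34908895 in BRQ, of which 99.5% to 99.6% lay on listed genes. These are the totals that the FPKM values were scaled by. Reads not counted towards them cannot be seen, so the sequencing depth may have been higher. The recovered reads served for depth, counting error and 1 added alternative, and the main test used FPKM. On simulated FPKM of the same genes the reads came back exactly for 99.2% of genes. Replicates of 1 group differed by more than counting noise (chi-square per gene 3.92 to 6.11), which does not tell separate cultures from repeat libraries of 1 RNA.

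Values were analysed as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, using eBayes with an intensity trend and group as the only term. The pseudocount makes fold changes of low genes smaller than they were. Genes with at least 0.5 FPKM in at least 3 of the 6 libraries were tested (12258 genes; 5077 were below), and p-values were two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. Ratios of means are ratios of mean FPKM. Tested on simulated data for the BRQ and DMSO comparison (12106 genes tested, dispersion 0.005), the fit recovered 40% of 50 genes changed 1.25-fold, 98% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold, and 8 of its calls (4.55%) were false.

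There were 35 gene lists fixed before the data were examined. The 30 with at least 5 tested members were tested with limma's camera at an inter-gene correlation preset at 0.01, adjusted over the lists, and again with the correlation estimated per list and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. On the simulated data, where genes varied independently and the other lists were left unchanged, camera called the 1 raised list of 30. In the real data 79.7% of tested genes changed, and estimated list correlations reached 0.287. The simulation therefore does not show the error rate of camera or of the gene test on the real data. Terms of the deposited annotation with 15 to 300 tested genes were tested with camera in the same way. The named genes were 15 genes fixed in advance, the 12 with the largest rise and the 12 with the largest fall among called genes with a mean of at least 1 FPKM and no overlap between groups, and up to 4 called members per list with the largest change; others are said to be chosen after their values were seen. Some of the genes picked by these rules are not reported here.

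Coordinates and spans come from a RefSeq table of GRCh38.p14, matched by Entrez ID for 17290 genes; GC content and strand come from GENCODE release 29, matched by symbol for 16860 genes. Of the 151 named genes matched there, 44 overlap another protein-coding gene, so their values are uncertain where reads were not counted by strand. Ratios against a group with 1 to 3 reads have an exact Clopper-Pearson 95% interval, and a group without reads was set to a floor of 3 reads over the group.

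The alternatives fixed in advance were pseudocounts of 0.1 and 1, no filter, a mean FPKM of at least 1, TMM factors, quantile normalization, no trend, array weights, the replicate number as a block, leaving out each library, and the other set tests. Added after the data were seen were limma-voom on the recovered reads, removal of the trend with genomic span, and a test of genes typed as protein-coding in the RefSeq table. Recovery of reads, annotation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.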

Results

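RNA was sequenced from A549 cells, an established human line derived from a lung adenocarcinoma, that had been given either the solvent DMSO or a compound abbreviated BRQ in the labels. The series title speaks of an inhibitor of DHODH, the mitochondrial enzyme that makes orotate during de novo pyrimidine synthesis, and BRQ is taken here to be that inhibitor, although the labels do not spell the abbreviation out. No dose or exposure time is stated in the labels. There were 3 libraries per group, and values below are mean FPKM ± SD (n = 3 libraries) or log2 fold changes of FPKM + 0.5, BRQ over DMSO. The library totals that the FPKM values were scaled by, worked back from the steps between low values, were 27789225, 29644462 and 28527046 reads in DMSO and 32910420, 32195353 and 34908895 reads in BRQ. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

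The libraries separated by treatment. Across tested genes, log2 values correlated at 0.996 to 0.997 within groups and at 0.919 to 0.927 between groups, and the first principal component, which parted BRQ from DMSO, held 94.1% of the variance. On the second component (1.69%) DMSO replicate 2 (-11.3) lay apart from DMSO replicates 1 (6.60) and 3 (4.83). Of 12258 genes tested, 9768 (79.7%) differed between BRQ and DMSO at an adjusted p under 0.05 in limma, with 5425 higher and 4343 lower in BRQ. At least 2-fold changes were seen for 1885 genes, of which 1258 were higher and 627 lower. A gene could pass the filter through its values in 1 group alone. Leaving out each library in turn gave 920 to 1281 genes at least 2-fold higher and 576 to 651 at least 2-fold lower. The 3 BRQ values lay entirely above or below the 3 DMSO values for 9973 genes (81.4%), where chance gives 10%. The median standard error of a log2 fold change was 0.07, so small differences passed the test, and the median log2 fold change of all tested genes was 0.07.

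**Figure D1:**
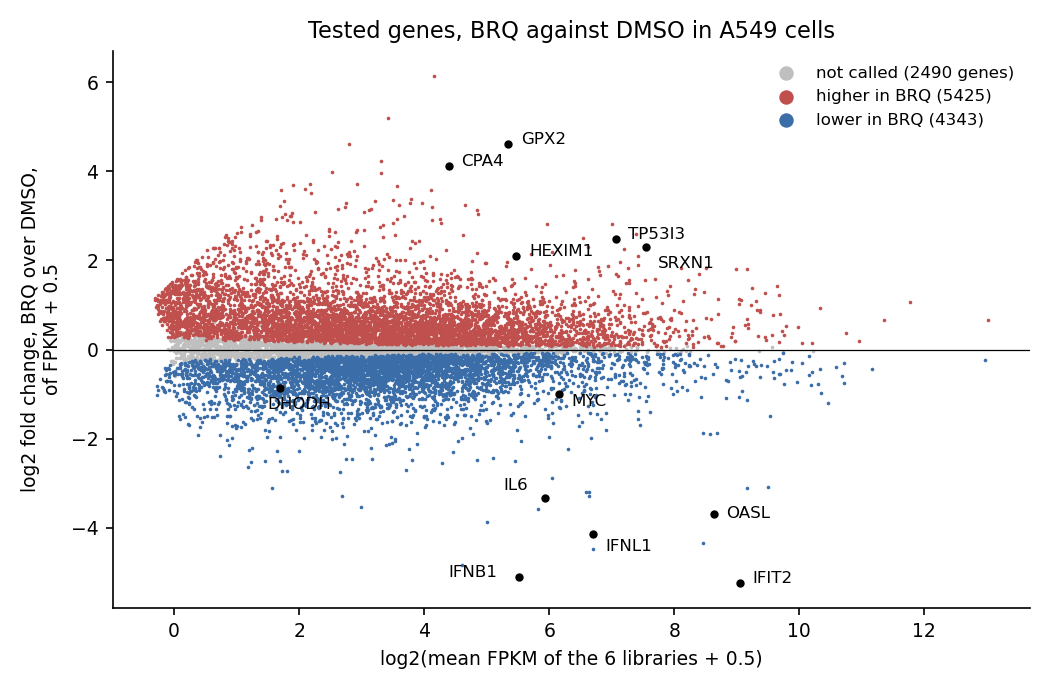
Log2 fold change of FPKM + 0.5, BRQ over DMSO, against log2 of the mean FPKM over the 6 libraries + 0.5, 1 point per tested gene. Red points are the 5425 genes called higher in BRQ, blue points the 4343 called lower and grey points those not called, and IFIT2 (log2 fold change -5.23) and IFNB1 (-5.10) lie lowest among the labelled genes.

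DHODH itself, on chromosome 16 from 72008744 to 72027659 (GRCh38), was lower in BRQ. Its level was 3.10, 4.13 and 3.72 FPKM in the DMSO libraries and 1.96, 1.38 and 2.04 FPKM in the BRQ libraries, a log2 fold change of -0.86 (SE 0.13, limma adjusted p = 0.000141), resting on 132 to 364 reads per library. CAD, which carries out the first steps of the same pathway, fell from 25.9 ± 0.697 to 12.3 ± 0.232 FPKM (log2 fold change -1.04). UMPS, which completes UMP, had 8.53 ± 0.478 and 7.56 ± 0.716 FPKM (log2 fold change -0.17, adjusted p = 0.0593; 0.00335 to 0.219 over the alternatives, with a call as lower under TMM factors, limma-voom and others), and CTPS1, which makes CTP from UTP, had 36.9 ± 2.43 and 35.6 ± 1.49 FPKM (adjusted p = 0.372; 0.0234 to 0.993 over the alternatives, with a call as lower only with the span trend removed). Of the 8 genes of the de novo pyrimidine list, 1 rose (CMPK1, log2 fold change 0.33), 3 fell (CAD, DHODH and NME1) and 4 were not called, and the counts were the same when adjusted over the list alone. The list as a whole was not called by camera (adjusted p = 0.329).

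Other nucleotide lists moved in both directions and none was called. In pyrimidine salvage, uptake and breakdown 8 of 13 tested genes rose and 4 fell. CDA, a cytidine deaminase, rose by 0.98 and the thymidine kinase TK1 by 0.62 on the log2 scale. DPYD, the enzyme that starts pyrimidine breakdown, fell by 1.19 and TYMP, thymidine phosphorylase, fell by 1.04. The DPYD gene spans 843 kb, and the 198 tested genes above 400 kb had a median log2 fold change of -0.65. Of 9 deoxynucleotide supply genes 5 rose and 2 fell, with the ribonucleotide reductase subunit RRM2 up from 22.3 ± 1.42 to 60.7 ± 2.18 FPKM and the thymidylate kinase DTYMK down (log2 fold change -0.76). Of 14 purine genes 3 rose and 7 fell, led by PFAS (-1.38) and PRPS2 (1.09). UDP-sugar and CMP-sugar genes rose in 14 of 21 cases and fell in 5, with CMAS (1.05), UGP2 (1.03) and UAP1 (1.01) rising most. CDP-lipid genes rose in 6 and fell in 5 of 12 cases, and their median (0.06) and mean (0.06) lay above 0 although camera, which compares a list with the other genes, placed them lower (adjusted p = 0.968). In all of these lists the counts adjusted over the list alone were the same.

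The genes that fell most were interferons, antiviral genes and cytokines. IFIT2, an antiviral RNA-binding protein on chromosome 10 (89302046 to 89309271, GRCh38), fell from 1028 ± 12.5 to 27.0 ± 1.26 FPKM, which is 38.1-fold lower (log2 fold change -5.23, SE 0.03, limma adjusted p = 7.27e-14). IFNB1, the interferon beta gene on chromosome 9 (21077104 to 21077942), fell from 88.4 ± 0.996 to 2.12 ± 0.417 FPKM, and IFNL1, a type III interferon, from 197 ± 2.23 to 10.7 ± 0.290 FPKM. The falls of these genes thus started from DMSO means of 88.4 to 1028 FPKM. The labels name no stimulus for the DMSO cultures, and whether they had met one was not tested. The antiviral genes RSAD2 (log2 fold change -4.47), IFIT3 (-4.34) and OASL (-3.70), the oxysterol-producing enzyme CH25H (-4.83), the chemokine CCL3 (-3.87) and the cytokine IL6 (-3.33) were also among the 12 largest falls. The remaining ones were HIP1R (-3.57), a clathrin-binding protein, TTC28 (-3.28), whose gene spans 702 kb, and CCL3L3 (-3.52), a near-identical copy of CCL3 whose value is uncertain because reads may have been divided between the copies.

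Among the 33 tested genes of the interferon-stimulated list 23 fell, 8 rose and 2 were not called, with a median log2 fold change of -0.59, and the counts were the same when adjusted over the list alone. The list was called lower by camera (adjusted p = 7.17e-05), but not when its inter-gene correlation was estimated (adjusted p = 0.137). The estimate was 0.0018, below the preset 0.01, which argues against a higher correlation as the cause of the lost call. ISG15 (log2 fold change -3.08) and the RNA sensors IFIH1 (-3.28) and DDX58 (-2.24) were lower. The 8 that rose were IRF7 (2.31), IFI27 (1.46), TRIM22 (1.26), OAS1 (1.14), BST2 (0.95), IFI6 (0.84), XAF1 (0.61) and IRF9 (0.41). MX1, an interferon-induced GTPase, had 4.05 ± 0.513 FPKM in DMSO and 3.67 ± 0.134 FPKM in BRQ (adjusted p = 0.230). These members, apart from IFIT2, IFIT3, RSAD2 and OASL, were named after their values were seen.

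**Figure D2:**
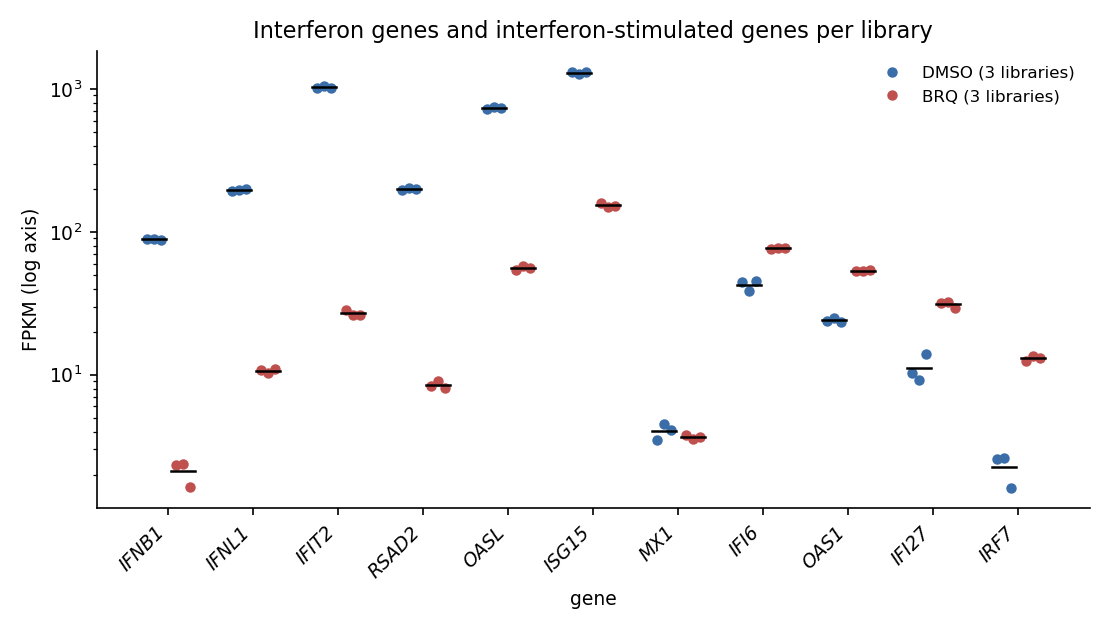
FPKM on a log axis of 11 interferon and interferon-stimulated genes, with 1 point per library (3 DMSO in blue, 3 BRQ in red) and a line at each group's mean. IFNB1 falls from a mean of 88.4 to 2.12 FPKM and IFIT2 from 1028 to 27.0 FPKM, whereas IFI6, OAS1, IFI27 and IRF7 lie higher in BRQ.

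Of the 12 genes with the largest rise, 3 had at most 3 reads in the DMSO libraries together. LOC105372440, a gene on chromosome 19 (50785728 to 50786160), had no reads in the DMSO libraries and 788 in the BRQ libraries together. Against a floor of 3 reads over the group it was 226-fold higher, and the exact Clopper-Pearson 95% lower bound was 183. FAM25A had 1 read in DMSO and 457 in BRQ, a ratio of 393 (exact Clopper-Pearson 95% interval 70.1 to 15548), and the antimicrobial ribonuclease gene RNASE7 had 3 and 871, a ratio of 249.5 (85.1 to 1212); floors and intervals cover counting error only. CCDC200 went from 0.0656 ± 0.0758 to 20.3 ± 2.36 FPKM. GPX2, a glutathione peroxidase on chromosome 14 (64939158 to 64942745), rose from 2.71 ± 0.640 to 77.5 ± 3.42 FPKM (28.6-fold, log2 fold change 4.62, SE 0.12, limma adjusted p = 4.49e-10). The others were C11orf86 (log2 fold change 4.24), the carboxypeptidases CPA4 (4.11) and CPM (3.67), the keratin KRT15 (3.98), C1orf116 (3.96), the cytochrome P450 gene CYP1A1 (3.72) and RASD1 (3.71), a Ras-related GTPase. LOC105372440, CCDC200, FAM25A, KRT15, RASD1 and RNASE7 passed the filter only through their BRQ values, so a rise was needed for them to be tested. GPX2 overlaps CHURC1, CPM overlaps MDM2 and RNASE7 overlaps NDRG2, each on the opposite strand, and whether reads were counted by strand is not given in the sources used here.

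Genes for making ribosomes were lower in BRQ. Of 34 ribosome biogenesis and RNA polymerase I genes 30 fell and 2 rose, with a median log2 fold change of -0.67. TAF1D, a subunit of an RNA polymerase I initiation factor, fell from 57.0 ± 3.79 to 10.3 ± 1.78 FPKM, and the ribosome assembly factors BOP1 (-1.62), NOP56 (-1.41) and BYSL (-1.35) fell as well. Of 58 cytosolic ribosomal protein genes 46 fell and 7 rose, with a median of -0.38; RPL23 fell from 254 ± 6.27 to 86.4 ± 1.05 FPKM, and RPL13A (-1.19), RPL24 (-1.06) and RPL10 (-1.06) followed. MYC, a transcription factor that drives ribosome production, fell from 94.8 ± 1.55 to 47.4 ± 1.34 FPKM (log2 fold change -0.99). Camera called both lists (adjusted p = 7.46e-09 for biogenesis and 4.16e-09 for ribosomal proteins), while the adjusted p with an estimated correlation was 0.137 and 0.435. Ribosomal protein genes have many processed pseudogenes, so their levels are uncertain where reads match several copies, and TAF1D overlaps 9 other genes on its strand.

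Of the lists that concern metabolism, NRF2 targets, cholesterol synthesis and glycolysis were called higher and the others were not. NRF2 target genes, which serve detoxification and glutathione metabolism, rose in 23 of 30 cases and fell in 7 (median log2 fold change 0.88). Their camera adjusted p was 0.000929, and 0.137 with an estimated correlation. That estimate was -0.0029, below the preset 0.01, which argues against a higher correlation as the cause of the lost call. Besides GPX2, SRXN1, a sulfiredoxin, rose from 62.2 ± 1.14 to 309 ± 3.68 FPKM and the aldo-keto reductase AKR1C1 from 51.8 ± 2.61 to 192 ± 7.61 FPKM, whereas HMOX1, heme oxygenase, fell from 600.1 ± 4.88 to 161 ± 7.45 FPKM. Cholesterol synthesis genes rose in 18 of 24 cases and fell in 2 (median 0.78, adjusted p = 0.000339; adjusted p = 0.152 with an estimated correlation), including the sterol reductase TM7SF2 (2.31), the isomerase IDI1 (1.96) and the sterol sensor INSIG1 (1.95).

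Glycolysis genes rose in 19 of 21 cases and fell in 1 (median 0.72, camera adjusted p = 0.000224), and hypoxia response genes rose in 12 of 14 cases and fell in 1 (median 1.31, adjusted p = 0.000929); for each the adjusted p with an estimated correlation was 0.435. The aldolase gene ALDOC rose from 1.85 ± 0.562 to 21.3 ± 0.969 FPKM, the phosphoglycerate kinase gene PGK1 from 78.1 ± 2.86 to 222 ± 9.08 FPKM and the monocarboxylate carrier SLC16A3 by 1.63 on the log2 scale. ALDOA (2.05) shares its locus with another coding gene on the same strand and was listed at only 3.14 FPKM in DMSO. In the hypoxia list the prolyl hydroxylase EGLN3 (2.85), the carbonic anhydrase CA9 (2.68), ANKRD37 (2.21) and NDRG1 (2.26, from 51.4 ± 14.9 to 241 ± 11.6 FPKM) rose most. DMSO replicate 2 was lower than the other DMSO libraries for several of these genes (NDRG1 34.1 FPKM against 59.8 and 60.2; EGLN3 2.64 against 5.23 and 5.03), and without it the hypoxia response list was still called (adjusted p = 0.000392; 0.000113 to 0.435 over the alternatives with camera). In these 4 lists the counts were the same when adjusted over the list alone.

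**Figure D3:**
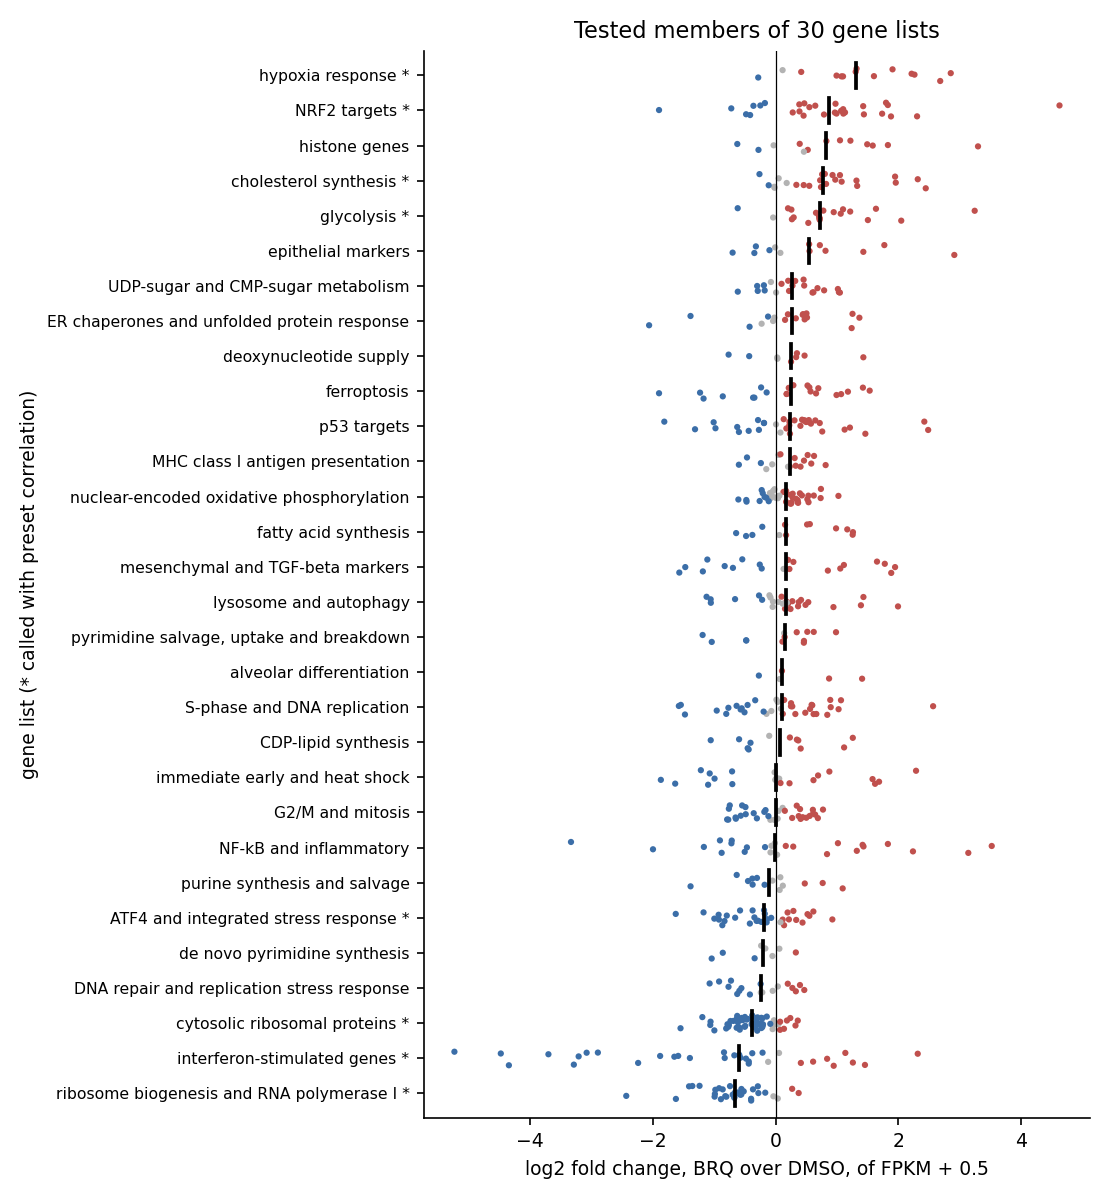
Log2 fold change of FPKM + 0.5, BRQ over DMSO, for each tested member of 30 gene lists, 1 point per gene, red if called higher, blue if called lower and grey if not called, with a bar at the list's median. An asterisk marks the 8 lists called by camera with a preset correlation, from a median of -0.67 for ribosome biogenesis to 1.31 for hypoxia response.

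The p53 targets moved in both directions. CDKN1A, the cyclin-dependent kinase inhibitor, rose from 162 ± 3.10 to 266 ± 6.43 FPKM. The list had 22 genes up and 11 down of 35 and was not called (median 0.23, camera adjusted p = 0.401). TP53I3 (2.48), the decoy receptor TNFRSF10C (2.42) and FDXR (1.46) rose, while the apoptosis gene PMAIP1 fell by 1.81 and the stress cytokine GDF15 fell from 208 ± 7.76 to 103 ± 1.64 FPKM. MDM2 had 58.0 ± 3.22 and 63.6 ± 1.63 FPKM (log2 fold change 0.13, limma adjusted p = 0.0159). The settings that ended this call included TMM factors (adjusted p = 0.190), quantile normalization (0.513) and no trend (0.0568). It also ended without DMSO replicate 3 (0.0616) or BRQ replicate 1 (0.0549). Over the alternatives the adjusted p ran from 0.000495 to 0.513. MDM2 overlaps CPM, which rose by 3.67 on the log2 scale, on the opposite strand. HEXIM1, an inhibitor of the transcription elongation factor P-TEFb, rose from 16.3 ± 0.425 to 71.7 ± 3.11 FPKM (4.40-fold).

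Cell cycle lists were split and not called. Of 36 S-phase genes 18 rose and 13 fell; the cyclin CCNE2 rose by 2.56 on the log2 scale, while the DNA polymerase subunit POLE (-1.57) and the replicative helicase subunits MCM5 (-1.54) and MCM2 (-1.47) fell. Of 34 G2/M genes 14 rose and 15 fell, among them CDC20 (-0.79), ECT2 (-0.77) and PRC1 (-0.76), which fell, and NEK2 (0.77), which rose. Histone genes rose in 9 of 13 cases and fell in 2 (median 0.83, camera adjusted p = 0.184), with H2BC4 up from 0.774 ± 0.384 to 11.7 ± 0.278 FPKM. Of 18 DNA repair and replication stress genes 5 rose and 9 fell (adjusted p = 0.233), led by the checkpoint kinase CHEK2 (-1.07). Counts adjusted over the list alone were the same for the p53 and cell cycle lists.

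Stress and immune lists differed in direction. The ATF4 and integrated stress response list had 22 genes down and 11 up of 34 and was called lower (median -0.18, camera adjusted p = 0.0428; adjusted p = 0.435 with an estimated correlation), with SARS1 (-1.63), ATF3 (-1.17) and the amino acid transporter SLC7A5 (-0.93) among the largest falls. That call ended without BRQ replicate 1 (adjusted p = 0.0862), 2 (0.0601) or 3 (0.0899). It also ended with a mean FPKM of at least 1 as the filter (0.0687). Without a BRQ library the filter of 3 libraries left 11723 to 11729 genes, against 12258, so the genes compared also changed. Over the alternatives with camera the adjusted p ran from 0.00607 to 0.435. Unfolded protein response genes rose in 11 of 18 cases and fell in 4 (adjusted p = 0.329); ERN1 (-2.06) and XBP1 (-1.38), the sensor and transcription factor of that response, fell, and the chaperones CRELD2 (1.36) and PDIA4 rose. MHC class I genes rose in 10 and fell in 3 of 17 cases (adjusted p = 0.329), with B2M, the MHC class I light chain, down from 1023 ± 13.2 to 741 ± 6.65 FPKM. CD274, the immune checkpoint ligand, rose from 4.64 ± 0.562 to 6.44 ± 0.304 FPKM. Ferroptosis genes rose in 14 and fell in 8 of 22 cases (adjusted p = 0.401); GPX4, the lipid peroxide-reducing enzyme, fell by 0.15, AIFM2, a ferroptosis suppressor, fell from 47.0 ± 2.26 to 20.6 ± 0.174 FPKM, and the cystine transporter SLC7A11 rose by 0.55 on the log2 scale. The NF-kB list had 11 genes up and 10 down of 25 (adjusted p = 0.746), and its median was -0.01 and its mean 0.25. IL1B (3.52), MMP1 (3.14) and CSF2 (2.24) rose, while IL6 (-3.33) fell. IL1B passed the filter only through its BRQ values, so a rise was needed for it to be tested. Immediate early and heat shock genes had 9 up and 8 down of 21 (adjusted p = 0.699, placed lower by camera with a median of 0.01), including HSPA1B (2.29), FOS (1.68), DUSP1 (-1.87) and KLF2 (-1.63).

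The remaining lists were not called by camera. Nuclear-encoded oxidative phosphorylation genes rose in 23 and fell in 9 of 42 cases (adjusted p = 0.329), with NDUFA2 (1.02) rising most. Fatty acid synthesis genes had 8 up and 4 down of 13 (adjusted p = 0.379), including the desaturase SCD, up from 98.1 ± 1.43 to 236 ± 7.46 FPKM. Lysosome and autophagy genes had 15 up and 6 down of 28 (adjusted p = 0.401), with the protease CTSL (1.39) and MAP1LC3B (1.43) up and GABARAPL1 (-1.12) down. Epithelial markers had 7 up and 4 down of 13 (adjusted p = 0.379), led by KRT19 (2.91), EPCAM (1.77) and CDH1 (1.43). Mesenchymal markers had 10 up and 9 down of 20 (adjusted p = 0.746, placed lower by camera with a median of 0.17). SNAI1 (1.78) and SNAI2 (1.65) rose, and the lowest log2 fold change of the list was -1.57. Its median was 0.0190 with quantile normalization. Of 5 tested alveolar genes 3 rose and 1 fell (adjusted p = 0.489), with LAMP3 (1.41) and NAPSA (0.87) rising. LAMP3 passed the filter only through its BRQ values, so a rise was needed for it to be tested. The calls for CAV1 (0.10) and AGER (-0.27) ended under other settings. Over the alternatives the adjusted p ran from 0.00356 to 0.709 for CAV1 and from 0.000198 to 0.218 for AGER. Markers of other cell types had too few tested genes for the set test. Those tested were higher in BRQ, but CD14, LUM and THY1 passed the filter only through their BRQ values, so a rise was needed for them to be tested, and of the 21 listed markers below the filter, which were not tested, 17 had a higher and 4 a lower mean FPKM in BRQ. The tested ones were CD68, CD14 and ITGAM among immune markers, COL1A1, LUM, THY1 and ACTA2 among fibroblast markers, and ESAM and EGFL7 among endothelial ones, and CD68 (146 ± 4.38 FPKM) and ACTA2 (19.5 ± 0.764 FPKM) were the highest in BRQ. The call for LUM ended with quantile normalization (adjusted p = 0.162; 0.000151 to 0.162 over the alternatives) and that for EGFL7 with the span trend removed (adjusted p = 0.208; 0.00260 to 0.208). No member of the mitochondrially encoded or nuclear-retained RNA lists had a value in the table.

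In the annotation of the deposited table, 73 of 2308 terms were called by camera, 36 higher and 37 lower in BRQ. Translation terms led the lower ones. In translational initiation 87 of 128 genes fell and 25 rose (adjusted p = 1.28e-05), and in rRNA processing 85 of 139 fell and 37 rose. Each had adjusted p = 0.777 with an estimated correlation. Aminoacyl-tRNA biosynthesis, RNA helicase activity and the spliceosomal complex were also lower. Among higher terms, all 24 called genes of the 27 tested for metabolism of xenobiotics by cytochrome P450 rose (adjusted p = 0.000238). In glycolysis and gluconeogenesis 39 of 45 rose and 3 fell, and in glutathione metabolism 34 of 39 rose and 4 fell. With an estimated correlation none of the terms and none of the 30 lists was called, the lowest adjusted p being 0.777 for terms and 0.137 for lists. Other ways of dividing the 6 libraries into 3 and 3 called up to 9 lists with the preset correlation, against 8 for the real division; each of those divisions still carries part of the difference between BRQ and DMSO, so they are not counts without a change.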

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

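The limma-voom fit on recovered reads, the removal of the span trend and the fit of RefSeq protein-coding genes were chosen after the data were seen; the other settings were planned. The number of genes changed between BRQ and DMSO stayed within 1.5 times the reported ones under each setting, from 8986 with a mean FPKM of at least 1 to 11010 without a filter, with 9875 under limma-voom and 9750 for RefSeq protein-coding genes only, and leaving out each library in turn gave 8880 to 9349. Those ranges were 1538 to 1867 for at least 2-fold changes, 7 to 8 for lists and -0.96 to -0.72 for the log2 fold change of DHODH. Without a BRQ library 11723 to 11729 genes passed the filter of 3 libraries, against 12108 to 12113 without a DMSO library. The tested genes therefore changed along with the libraries. TMM factors and quantile normalization moved the median of all genes from 0.07 to 0.01 and -0.02 and the share of calls that were higher from 55.5% to 50.1% and 48.7%. The number of called lists fell from 8 to 0 with an estimated correlation and rose to 26 with fry, which asks another question. Called terms fell from 73 to 0 with an estimated correlation. For the interferon-stimulated and NRF2 lists the estimates (0.0018 and -0.0029) lay below the preset 0.01, which argues against a higher correlation as the cause. Camera with an estimated correlation therefore differed from the preset version in more than the correlation. A lost call there does not by itself show that the genes of a list move together. For the other called lists the estimates were 0.0189 to 0.251, and otherwise the cause was not tested.

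Same-numbered samples did not deviate together (correlations of -0.02, -0.01 and -0.04). The values thus show no pairing, but they cannot tell whether same-numbered samples were handled together. With the replicate block 9629 genes changed between BRQ and DMSO, 9547 of them also without it.

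The direction of some list tests turned, all for lists not called; the cause was not tested. CDP-lipid synthesis turned to higher, with medians of 0.0650 with a mean FPKM of at least 1 and with fry, -0.00391 with TMM factors, 0.0421 with quantile normalization, 0.0670 with limma-voom, 0.0806 without DMSO replicate 2, and 0.0535, 0.0940 and 0.0475 without BRQ replicates 1, 2 and 3. S-phase and DNA replication turned to lower without a filter (median 0.10) and with the span trend removed (0.0241), as did oxidative phosphorylation with the span trend removed (0.0185); the NF-kB list turned to higher with fry (median -0.0109). Among genes, CAV1 went from 0.10 to -0.0144 with quantile normalization and the uncalled CTPS1 from -0.05 to 0.000502 without DMSO replicate 2 and -0.0884 without DMSO replicate 1. Of the values of named genes under other settings 2779 kept their direction and side of the threshold, 19 lost and 7 gained a call. Depth limits low genes, and the 5077 below the filter were not tested. Count-model fits were planned only for a table of whole-number counts and were not run. The recovered reads were fitted with limma-voom.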

Other observations

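The tests on leukocyte transcripts and on genes that depend on secreted interferon, the list of genes that IRF3 can induce, and the removal of smooth trends with length, GC content and level, were chosen only after the result was seen, as were the genes named in this part. The NF-kB list was not called, and its members went both ways. IL1A (log2 fold change 1.83), the adhesion molecule ICAM1 (1.42), TNF (1.43), CCL2 (1.32) and CCL20 (1.02) rose with IL1B, while CXCL2, TNFAIP3 (-1.17), SOD2 (-0.88), PTGS2 (-0.71) and CXCL8 (-0.50) fell with IL6.

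In the term antibacterial humoral response 18 of 19 tested genes rose and 1 fell (camera adjusted p = 0.00356, and 0.777 with an estimated correlation), among them the protease inhibitors PI3, from 6.62 to 33.2 FPKM, and SLPI, from 10.6 to 34.3 FPKM. Complement and coagulation genes rose in 26 of 36 cases and fell in 6 (adjusted p = 0.0428; 0.777 with an estimated correlation), with the complement protease C1S rising from 23.3 to 108 FPKM and the complement component C3 from 20.8 to 63.0 FPKM. In xenobiotic metabolism ALDH3A1 (1.83), EPHX1 (1.43) and UGT2B7 (2.61) rose beside CYP1A1. Of the aminoacyl-tRNA synthetases YARS1 (-1.45), FARSB (-1.45) and GARS1 (-0.83) fell.

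A first pattern was that interferons and genes that the transcription factor IRF3 can induce directly were lower in BRQ. A list of 17 such genes, from IFNB1, IFNL1 and CH25H to ISG15 and CCL5, was drawn up after the largest falls were seen and so restates them (17 lower, median log2 fold change -3.20). Scaling between libraries is argued against, since the median of the interferon-stimulated list stayed at -0.65 or below under TMM factors and quantile normalization, and so are leukocytes in the DMSO cultures, since the highest of 5 leukocyte transcripts reached 0.0138% of the level of CCL5 there (PTPRC 0.00556, CD74 0.105 and FCER1G 0.141 FPKM against 1025 FPKM). Less signalling by secreted interferon stays open. Of 15 tested interferon-dependent genes 33.3% were called lower and 8 higher (median log2 fold change 0.41), which goes against it. Of the 8, XAF1 (0.339 FPKM in DMSO), BST2 (0.508) and TRIM22 (0.808) had little room to fall. The others of the 8 had 2.52 to 42.7 FPKM in DMSO. By contrast, of the 25 genes of the fixed list outside the IRF3 list 60% were lower and 8 higher (median -0.44). Of those 25, 14 were shared with the interferon-dependent set. Whether the DMSO cultures had met an interferon-inducing stimulus that the labels do not mention was not tested, and an effect of BRQ on this induction stays open as untested.

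A second pattern was that genes with a long genomic span were lower in BRQ. The median log2 fold change went from 0.24 for genes under 5 kb to -0.29 for 200 to 400 kb and -0.65 above 400 kb (198 genes), and genes of at least 200 kb lay 0.55 below those under 20 kb (difference -0.55, 95% bootstrap interval -0.61 to -0.48). GC content and low expression are argued against as the whole cause, since within 3 equal groups of genes the smallest difference was -0.49 for GC content and -0.50 for mean FPKM. Exonic length cannot be told apart from span in full, although a difference remained in each of the 3 groups by exonic length. It was -0.68 (interval -1.06 to -0.46) in the shortest, -0.30 (-0.49 to -0.12) in the middle and -0.44 (-0.54 to -0.32) in the longest group. With the length trend removed from all genes it was -0.24 (-0.32 to -0.18). An effect of BRQ on the transcription of long genes was not tested and stays open.

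Another pattern was that more genes had reads in BRQ, 16162 to 16244 against 14918 to 14935 in DMSO. Sequencing depth is argued against, since with each library thinned to 27789225 reads the lowest BRQ library still had 1121 genes more than the highest DMSO library. Genomic DNA in the BRQ libraries is argued against as well: olfactory receptor genes gained 0.0414 times as much FPKM as other low genes when unlisted genes count as 0, and 0.231 times (interval 0.0599 to 0.422) among listed genes. Read-through from an expressed upstream neighbour would need more such neighbours near the 1308 low genes that gained at least 4-fold, and the odds ratio was 0.679 (0.516 to 0.888). RNA carried over from other cells was not tested, nor was an effect of BRQ on the transcription of low genes, and both stay open.

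The 6 libraries can be divided into 3 and 3 in only 10 ways, too few for a share under 0.05. The real division gave 9768 changed genes and 1885 changed at least 2-fold, each in 1 of the 10 divisions, and the highest of the others gave 0 for both in limma. Those other divisions place the difference between BRQ and DMSO inside their groups as spread. Their 0 was therefore to be foreseen and does not measure chance. For lists the real division gave 8 and the highest of the others 9, and 3 of the 10 gave at least 8; the other divisions still carry part of the difference between BRQ and DMSO, so theirs are not counts without a change.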
